A study of Homo sapiens with 6 samples.

How the data were processed

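RNA and PLA libraries came from human blood mononuclear cells that were thawed and rested overnight, per the labels' protocols. There were 3 conditions (donor 1 untreated, donor 1 with ConA for 24 h, donor 2 untreated), each with 1 RNA and 1 PLA library. Both conditions of donor 1 were processed in the same run and donor 2 in another, per the labels. The RNA files hold UMI counts per gene and cell as deposited, made with Cell Ranger 8.0.1 on GRCh38, per the file headers, with bcl2fastq and Seurat also named in the submitters' processing notes. Gene symbols are those paired with Ensembl identifiers in the deposited feature lists. The PLA files hold counts per product and cell as deposited, where a product is an ordered pair of probes joined by ligation. How PLA reads were assigned to products and whether they were collapsed by UMI is not given in the sources used here, so they are called PLA counts. Panels shared 44 probes (30 antibodies, 13 lectins and a free oligonucleotide), with 15 more in the donor 1 run (13 antibodies, PHA-E and UEA-I) and 10 more antibodies in the donor 2 run. Alternative names of CD29, CD49e and LAG-3 were merged, although clones may differ, and Galectin-3 stands on the lectin side, with its reagent not given in the sources used here.

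The RNA files held 9915, 9927 and 10335 barcodes (donor 1 untreated, donor 1 ConA, donor 2) with 73000183, 81911343 and 79367769 UMIs. Cells with at least 500 genes and at most 15% mitochondrial UMIs numbered 9516, 9579 and 9995. Scrublet's automatic threshold called 1, 0 and 1025 doublets and was judged to have failed, so the top 8% of scores per library were left out (761, 766 and 800 cells). Kept cells held 8578033, 5587108 and 13779906 PLA counts over 1336, 1292 and 1149 products, and 8746, 8811 and 9192 of them had PLA counts. Free oligonucleotide stood second in 6.49%, 4.15% and 0.755% of counts, and the top 1% of cells held 5.92%, 8.58% and 4.22%.

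Each RNA library was clustered alone with scanpy 1.11.5 and leidenalg 0.10.2 (Python 3.11.15, numpy 2.4.6, scipy 1.17.1, pandas 2.3.3, scikit-learn 1.9.0). Counts were scaled to 10000 per cell and log transformed, and 2000 variable genes, 30 principal components, 20 neighbours and Leiden resolution 1.5 were used. Glycosylation genes, mitochondrial, ribosomal protein, HLA and KIR genes, receptor variable segments and sex-linked genes were kept out of the variable genes. Clusters were named from RNA only. Marker lists were CD3D, CD3E, CD3G, TRAC, CD2, CD5 and CD6 for T cells, KLRF1, KLRD1, NCAM1, NCR1, SH2D1B, GNLY, SPON2, FCER1G and TYROBP for NK cells, MS4A1, CD79A, CD79B, BANK1, PAX5, CD22 and FCRLA among others for B cells, and LYZ, CD14, FCN1, VCAN, CSF1R, CD68, SPI1, MS4A7, MS4A6A, CTSS and CST3 for monocytes. The score of a cluster is the mean over markers of its log2 CPM (10 added) minus the mean of all clusters. A cluster took a lineage at a score of at least 1.5 with a T score below −0.5, and other clusters were T cells at a T score of at least −0.5 with an NK score under 2.5 and other scores under 1. A name also needed 3 detected markers and no more markers of another class than of its own among the 10 top genes by fold against all other cells (50 CPM added). T cells were clustered again, called CD4 at a log2 CD8 over CD4 ratio up to 0 and CD8 from 3. Naive-like clusters scored higher for CCR7, LEF1, TCF7, MAL, NOSIP, TXK, ACTN1 and BACH2, and memory-like clusters for S100A4, ANXA1, ANXA2, IL32, AQP3, ITGB1, CRIP1 and GPR183 or, in CD8, also CCL5, GZMK, GZMA, GZMH, NKG7, PRF1, CST7, FGFBP2 and KLRG1, by a margin of 0.3. Clusters with a regulatory score of at least 1.5 or an innate-like score of at least 1 were set apart first, and CD4 clusters with a cytotoxic score of at least 1 got no state. Markers were FOXP3, RTKN2, IKZF2 and TIGIT for regulatory and TRDC, TRDV2, TRGV9, TRGC1, SLC4A10, ZBTB16 and NCR3 for innate-like T cells. The naming rule was tightened after cluster scores were seen and before PLA counts by class were seen. Plasma cell, dendritic cell, platelet and red cell markers named no class that is reported. T cells given no state made up 24.2%, 24.5% and 29.5% of cells, regulatory T-like cells 1.38%, 1.65% and 0.653%, and innate-like T cells 5.03%, 5.07% and 0%. The 4 states held 1693, 1208 and 2247 (CD4 naive-like), 1305, 1557 and 1587 (CD4 memory-like), 471, 799 and 1083 (CD8 naive-like) and 1262, 1245 and 746 cells (CD8 memory-like).

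T cell states were compared because the series concerns glycan remodelling in T cell differentiation. Counts were summed per state and untreated donor into 8 sums, scaled by TMM, filtered by filterByExpr and fitted with edgeR 4.0.16 (limma 3.58.1, R 4.3.3) by quasi-likelihood with donor as a block, leaving 3 residual degrees of freedom. Pairing rests on the labels and the barcodes, since the states of a donor come from the same library. Contrasts were memory-like minus naive-like in CD4 and in CD8, and p was adjusted by Benjamini-Hochberg over probes (44), pairs with both orders added (345) or all tested genes (17950) at a threshold of 0.05. DESeq2 1.42.0 served as a second tool. ConA and donor comparisons had 1 library per arm, so class sums were compared as CPM ratios for RNA and as counts per cell and shares for PLA, with exact conditional binomial 95% intervals. List medians were set against 10000 random lists of the same size matched in 20 bins of mean expression. Fold changes against 0 counts are bounds with a floor of 3 counts. Observed over expected divides a pair's summed count by the sum over cells of the product of its 2 probe totals over the cell total. Figures were drawn with matplotlib 3.10.9.

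Named genes followed a rule fixed before the data were examined, as were the tests, marker lists, gene lists and most alternatives. After ConA these were the 12 highest and 12 lowest genes in T cells and the 5 highest and 5 lowest in NK and B cells, with at least 50 counts and at least 2-fold above or below both untreated libraries, ranked with 0.5 counts added. For donor 2 against donor 1 they were the 5 highest and 5 lowest in T cells and monocytes. Marker genes, sex-linked, HLA, KIR, GSTM1, ERAP2, variable segment, mitochondrial, ribosomal and clone-named genes were left out, and 3 further donor 2 genes were left unnamed after being seen because they could belong to one person. Up to 4 members per list were eligible, every lectin, and the 8 probes and 10 pairs with the largest change among those with at least 100 counts or past the threshold with the same sign in both donors. Gene lists covered activation receptors, activation transcription factors, cytokines and chemokines, interferon response, interferon-γ targets, cell cycle, ribosome biogenesis, glycolysis, cytotoxic effectors, chaperones of the endoplasmic reticulum, heat shock and dissociation genes, platelet genes, red cell genes and mitochondrially encoded genes. Glycosylation lists covered N-glycan processing, oligosaccharyltransferase and precursor genes, sialylation, O-glycans, galactose and N-acetyllactosamine, fucosylation, nucleotide sugars and lectins.

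Tests were tried on simulated data with planted changes, drawn from the mean levels, depths and fitted dispersion trend of these libraries. For probes only 2 were planted at 4-fold and 3 at 2-fold per contrast. Recovery was 100% at 4-fold in both contrasts, and 0% (CD4) and 66.67% (CD8) at 2-fold. For pairs, 78.8% and 69.7% of 4-fold and 24.2% and 6.06% of 2-fold changes were recovered (33 planted of each), with 0 false among 34 and 1 among 27 calls. For RNA the values were 89.4% and 78.8% at 4-fold and 31.3% and 22.4% at 2-fold (66 and 67 planted), with 1 false among 83 and 6 among 76 calls. At 1.5-fold, at most 4.48% were recovered in any of these tests. RNA ratio intervals held the true ratio for 95.26% of 16851 genes. Pairs planted at 2-fold and 3-fold enrichment were measured at 1.69 and 2.85, and unchanged pairs at 0.852 to 1.10, so observed over expected runs low at 2-fold.

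Alternatives covered the tool, relative log expression and library total scaling, cell numbers as library size, no filter on low counts, no donor block, ConA as a further block, leave-one-out, joint clustering of all libraries, cells with at least 200 genes and up to 25% mitochondrial UMIs, doublets kept, TMM scaling of RNA ratios, a minimum of 200 counts, PLA shares, thinning to 200 PLA counts per cell, medians over cells, pooled margins and pair orders kept apart. After the data had been seen, the looser filter and doublets kept were added for T states, leaving out the top 1% of cells for PLA ratios, and shares, thinning and medians for donor 2. Interaction and lineage fits were also chosen then. A few genes and probes that the naming rule picks are not reported here, although counts and list results include them. PLA ratios of donor 2 in NK and B cells are not reported, since several turned direction between counts per cell and shares.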

Results

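Peripheral blood mononuclear cells of 2 donors were measured by single-cell RNA sequencing together with proximity ligation (PLA) products that pair antibodies with lectins on the same cell. Donor 1 gave an untreated library and a library after 24 h with concanavalin A (ConA), a mannose-binding lectin that stimulates T cells. Donor 2 gave an untreated library from a separate run, so donor and run cannot be told apart. After filtering, 8755, 8813 and 9195 cells remained in donor 1 untreated, donor 1 ConA and donor 2, with median RNA UMI counts of 6665, 5321 and 7074 per cell. Median PLA counts per cell were 783, 396 and 1173.5 in the same order. An antibody came first and a lectin second in 93.0%, 94.9% and 98.3% of PLA counts.

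T cells made up most of each library, at 84.6%, 85.8% and 91.8% of cells (95% binomial intervals 83.9 to 85.4, 85.01 to 86.5 and 91.2 to 92.3). NK cells, the cytotoxic innate lymphocytes, were 13.8% (13.0 to 14.5) of untreated donor 1 cells, 10.8% (10.2 to 11.5) after ConA and 1.87% (1.60 to 2.17) in donor 2. B cells were few, with 42, 146 and 69 cells. Monocytes numbered 35 in untreated donor 1 and 147 in donor 2, and no cluster was named monocyte after ConA. Clusters given no class held 0.731%, 1.76% and 4.002% of cells, and after ConA they included 36 cells with a monocyte score of 1.55 but a T score (−0.475) above the limit for that name. Each condition had a single library, so class shares and all comparisons of ConA or of donors were left untested, and their intervals carry counting error only. The largest T cell clusters of untreated donor 1 were marked by ADAM23 and SPON1 (1165 cells), by TSHZ2, LEF1 and CCR7 (786 cells) and by CCL5 and NKG7 (684 cells). After ConA the largest were marked by IL17F, TNFRSF4, CCL20 and IL2RA (903 cells), by FABP5, HMGA1 and HSPD1 (778 cells) and by CCL4, CCL3, LAG3 and TNFRSF9 (544 cells).

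In CD4 T cells, memory-like cells carried more PHA-L and AAL signal than naive-like cells and less CD38, CD45RA, CCR7 and CD27 signal. PHA-L, which binds β1,6-branched N-glycans, rose by log2 0.99 (SE 0.26, adjusted p = 0.0400; donors 0.77 and 1.25). AAL, which binds fucose, rose by 0.93 (SE 0.26, adjusted p = 0.0432; donors 1.02 and 0.82). CD38, an NAD-consuming ectoenzyme, fell by 3.21 (SE 0.57, adjusted p = 0.00720), and CD45RA, the long phosphatase form of naive cells, fell by 2.59 (SE 0.38, adjusted p = 0.00515). CCR7, the lymph node homing receptor, fell by 2.999 (SE 0.40, adjusted p = 0.00515), and the costimulatory receptor CD27 fell by 1.31 (SE 0.22, adjusted p = 0.00720), whereas CD28 did not pass (log2 −0.11, adjusted p = 0.796). The T cell receptor chain complex CD3 (log2 −1.29, adjusted p = 0.0385) also fell. The integrin chains CD29 (log2 1.04, adjusted p = 0.00720) and CD49e (log2 0.96, adjusted p = 0.0432) and the adhesion molecule ICAM-1 (log2 1.14, adjusted p = 0.0432) rose. CCR7 and ITGB1 (CD29) RNA helped to name the states, so those 2 results are in part built in. The other lectins did not pass: LEL 0.55, Galectin-3 0.77, GSL-II 0.42, ConA 0.35, PNA 0.29, DBA 0.21, SNA −0.03, MAL-I −0.21, ECA −0.24, MAL-II −0.29 and DSL −0.56, with adjusted p from 0.0641 to 0.869. In all, 11 of 44 probes passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p below 0.05, 5 higher and 6 lower. The split was 12 higher and 5 lower with cell numbers as library size. It was 1 higher and 5 lower with relative log expression scaling, so at most 1 of CD29, CD49e and ICAM-1 passed there. PHA-L and AAL did not pass with that scaling (adjusted p = 0.0544 and 0.0714; over all alternatives 0.00930 to 0.162 and 0.00593 to 0.162), and LEL passed with library totals (adjusted p = 0.0411; over all alternatives 0.0116 to 0.565). DSL (0.00679 to 0.471), Galectin-3 (0.0115 to 0.783), ConA (0.0132 to 0.482), GSL-II (0.0364 to 0.755), PNA (0.0384 to 0.820) and MAL-II (0.0440 to 0.887) also had an adjusted p below 0.05 under at least 1 alternative.

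In CD8 T cells the lectin pattern differed: memory-like cells carried more LEL and MAL-I signal and less MAL-II, DSL, ECA, PHA-L and SNA signal. LEL, a lectin for poly-N-acetyllactosamine chains, rose by log2 1.84 (SE 0.18, adjusted p = 0.000292; donors 2.04 and 1.62). MAL-I, which prefers α2,3-sialylated N-acetyllactosamine, rose by 0.82 (SE 0.17, adjusted p = 0.00607). MAL-II, a lectin for α2,3-sialylated O-glycans, fell by 1.79 (SE 0.16, adjusted p = 0.000247; donors −1.84 and −1.75). DSL, which binds GlcNAc oligomers, fell by 1.65 (SE 0.20, adjusted p = 0.000573), and ECA, which binds terminal N-acetyllactosamine, fell by 1.64 (SE 0.24, adjusted p = 0.00147). PHA-L fell by 1.12 (SE 0.26, adjusted p = 0.0106; donors −1.41 and −0.88) and SNA, a lectin for α2,6-sialic acid, by 0.68 (SE 0.17, adjusted p = 0.0118). With library totals as scaling, PHA-L (log2 −0.57, adjusted p = 0.125; over all alternatives 0.00164 to 0.125) and SNA (log2 −0.14, adjusted p = 0.539; 0.000384 to 0.539) did not pass and AAL (log2 0.95, adjusted p = 0.0211; 0.0135 to 0.406) did, whereas LEL, MAL-I, MAL-II, DSL and ECA passed under every scaling tried. Without the donor block MAL-II did not pass (adjusted p = 0.0571; over all alternatives 2.56e-18 to 0.0571). With TMM scaling AAL (0.40), Galectin-3 (0.33), ConA (0.24), GSL-II (0.02), PNA (0.01) and DBA (−0.48) did not pass, with adjusted p from 0.143 to 0.998, although each passed under at least 1 alternative (lowest adjusted p 0.00270 for ConA and 0.0358 for DBA). The CD8 change differed from the CD4 change for PHA-L (log2 −2.11, adjusted p = 0.0135), MAL-II (−1.50, adjusted p = 0.0126) and LEL (1.29, adjusted p = 0.0150) when the difference itself was tested, a test chosen after these results were seen. The CD8 memory-like class could also be named by cytotoxic genes, whereas cytotoxic CD4 clusters got no state, so the 2 classes are not matched in effector cells.

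Among antibody probes in CD8 T cells, CD56, CD16, CD11c, PD1 and CD11b rose most and CCR7, CD27 and CD28 fell most. CD56, an adhesion molecule of NK cells, rose by log2 3.36 (SE 0.50, adjusted p = 0.00147). The Fc receptor CD16 (log2 2.72, adjusted p = 0.0225; donors 0.96 and 3.86), the integrin chains CD11c (log2 2.45, adjusted p = 0.00147) and CD11b (log2 2.19, adjusted p = 0.00470) and the inhibitory receptor PD1 (log2 2.32, adjusted p = 0.0118) rose. CCR7 fell by 4.04 (SE 0.42, adjusted p = 0.000292), CD27 by 2.74 (SE 0.23, adjusted p = 0.000247) and the costimulatory receptor CD28 by 2.24 (SE 0.34, adjusted p = 0.00147). The integrin chains CD49e (log2 1.51, adjusted p = 0.00373) and CD29 (log2 1.21, adjusted p = 0.00147) and ICAM-1 (log2 1.21, adjusted p = 0.0154) rose as in CD4 cells. The CCR7 and CD29 results are in part built in here too. CTLA-4 (log2 −0.96, adjusted p = 0.0123), CD45RA (log2 −1.31, adjusted p = 0.0199), CD45RO (log2 −0.78, adjusted p = 0.0222), CD8 (log2 −1.06, adjusted p = 0.0212; a marker of the class) and the free oligonucleotide (log2 −0.56, adjusted p = 0.0286) fell with TMM scaling. With library totals these 5 did not pass (adjusted p = 0.0653, 0.108, 0.281, 0.130 and 0.940). Per cell, CD8 (log2 0.14) and CD45RO (0.25) were higher in memory-like cells of donor 1, and the free oligonucleotide (0.19) in those of donor 2. CTLA-4 and CD45RO gave 0.0753 to 0.295 counts per cell, against 0.133 for the highest isotype control in donor 2 T cells. Together 23 of 44 probes passed, 10 higher and 13 lower, and all 23 had the same sign in both donors on the TMM scale. The split depended on scaling, with 18 higher and 6 lower by library totals. These tests compare 8 sums from 2 donors and have 3 residual degrees of freedom.

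**Figure D1:**
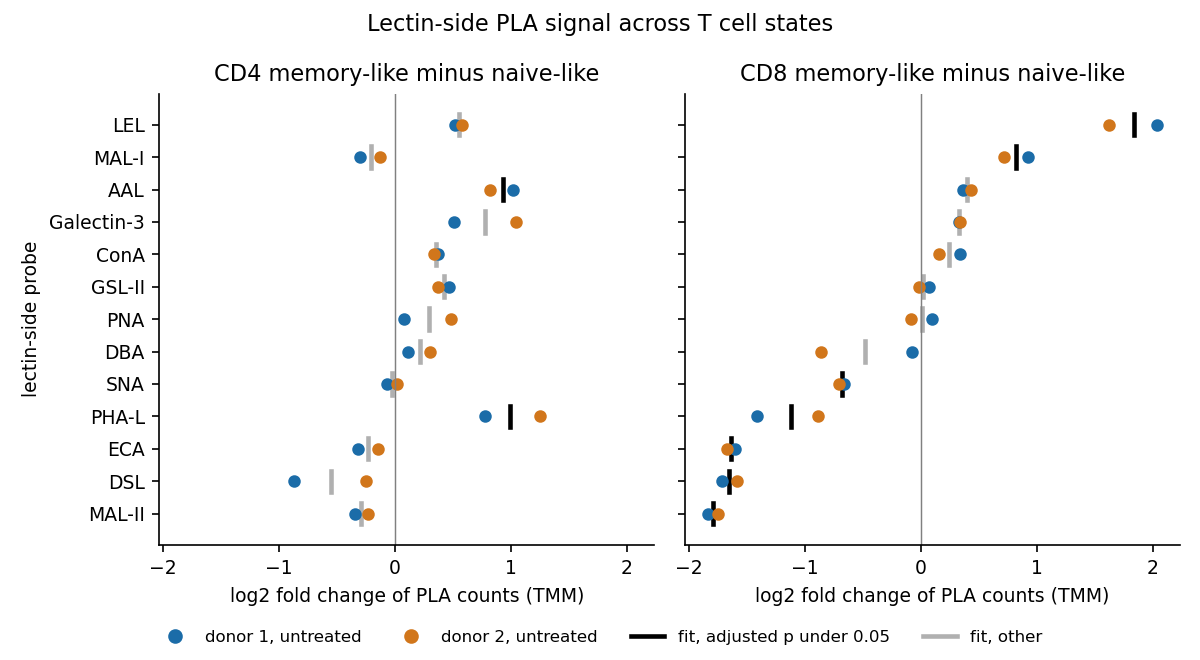
Lectin PLA counts in memory-like minus naive-like cells (log2 fold change, TMM scaling) for CD4 and CD8 T cells, with a dot per donor and a bar for the fit, black where the adjusted p is below 0.05. LEL moves by 1.84 in CD8 and by 0.55 in CD4, and PHA-L has opposite signs.

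The antibody-lectin pairs with the largest changes were those of antibodies whose own signal also changed. In CD4 memory-like cells the strongest falls were on CD38, with MAL-II (log2 −4.59, SE 0.54, adjusted p = 0.00197), ECA (−4.40, SE 0.65, adjusted p = 0.00210), DSL (−3.94), SNA (−3.89), ConA (−3.53) and AAL (−3.50, adjusted p = 0.00818). CCR7 with MAL-I (−3.58) and MAL-II (−3.47) and CD45RA with MAL-II (−3.38) fell as well. In CD8 memory-like cells CCR7 fell with ECA (−4.71, SE 0.66, adjusted p = 0.000884), DSL (−4.56, adjusted p = 0.000301), PHA-L (−4.45), MAL-II (−4.34) and ConA (−4.21). CD56 rose with MAL-I (4.32, SE 0.63, adjusted p = 0.00103), AAL (4.23, adjusted p = 0.00728; donors 1.58 and 6.14), SNA (4.03) and ConA (4.02), and PD1 rose with MAL-I (4.04, adjusted p = 0.00237). Since CCR7 RNA helped to name the states, its pairs are in part built in. Counted by lectin, 16 of 30 LEL pairs tested rose in CD8 cells against 1 that fell, and 14 of 30 MAL-I pairs against 3. Of 30 MAL-II pairs 5 rose and 17 fell, of 30 DSL pairs 5 and 15, of 23 ECA pairs 1 and 13 and of 28 PHA-L pairs 4 and 11. In CD4 cells 8 of 28 PHA-L pairs rose and 3 fell, and 8 of 30 MAL-II pairs fell. By edgeR's quasi-likelihood test 66 of 345 pairs passed in CD4 (21 higher, 45 lower) and 163 in CD8 (80 higher, 83 lower). Library totals gave 107 higher and 52 lower in CD8, and cell numbers gave 54 higher and 43 lower in CD4.

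Glycosylation RNA also differed between memory-like and naive-like CD8 cells. B4GALT5 (log2 1.90, adjusted p = 0.00758), B4GALT1 (1.25, adjusted p = 0.0107) and B4GALT4 (0.85), which add galactose, rose, as did B3GNT2 (0.69, adjusted p = 0.0451), which extends poly-N-acetyllactosamine. B3GNT7 and B4GALT6 had no counts in naive-like cells of either donor and were at least 16.9-fold and 21.7-fold higher in memory-like cells (floor of 3 counts over the group; adjusted p = 0.0101 and 0.00654). GALNT3 (4.82, SE 0.38, adjusted p = 0.000367), GALNT6 (1.76) and GALNT2 (0.94), which start O-glycans, rose, and the core branching enzyme GCNT4 fell (−2.79, adjusted p = 0.00522). Among sialyltransferases ST8SIA6 (4.54, SE 0.71, adjusted p = 0.00608), ST8SIA1 (2.74), ST6GALNAC6 (1.46) and ST8SIA4 (1.35) rose, whereas ST6GALNAC3 fell (−4.09, SE 0.29, adjusted p = 0.000250), and so did the sialic acid esterase SIAE (−1.24). Of 15 N-glycan processing genes tested, 3 fell, the mannosidase MAN1C1 (−2.87), the branching enzyme MGAT4A (−0.94, adjusted p = 0.0124) and the core fucosyltransferase FUT8 (−0.82), while MGAT1 rose (0.93). Galectin genes LGALS3 (3.93, adjusted p = 0.0259) and LGALS1 (3.71, adjusted p = 0.00245), the lectin receptors KLRB1 (3.31) and KLRG1 (3.08, a marker of the class) and the selectin ligand SELPLG (1.24) rose, and LGALS3BP (−4.14) fell. Rises were also seen for the hexosamine enzyme GFPT2 (2.43), the fucosyltransferase FUT11 (0.91), the lysosomal glycosidases NEU1 (1.24) and GLB1 (1.06) and the O-GlcNAc hydrolase OGA (0.71).

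Fewer glycosylation genes passed between the CD4 states. LGALS3 (log2 3.96, SE 0.64, adjusted p = 0.0251), KLRB1 (3.41, SE 0.46, adjusted p = 0.0156) and LGALS1 (3.06, SE 0.44, adjusted p = 0.0179) rose, as did GALNT3 (1.89), GALNT6 (1.44), GALNT10 (1.08), B4GALT5 (1.77) and GLB1 (1.27). ST6GALNAC3 (−3.87, SE 0.29, adjusted p = 0.00358), GCNT4 (−2.10) and the mannosidase MAN2A1 (−1.06) fell. Of 147 glycosylation genes among 17950 tested, 12 passed in CD4 (8 higher, 4 lower) and 32 in CD8 (24 higher, 8 lower) by edgeR's quasi-likelihood test with adjustment over all genes. Adjusted over the list alone, 10 were higher and 4 lower in CD4, and 25 higher and 11 lower in CD8. The share of all 17950 genes that passed is not given here. These counts therefore do not show whether glycosylation genes differed more often than other genes. By gene group, the numbers higher and lower in CD8 were 7 and 0 of 17 for N-acetyllactosamine, 5 and 2 of 24 for sialylation, 3 and 1 of 16 for O-glycans, 1 and 3 of 15 for N-glycan processing, 5 and 2 of 11 for lectins, 2 and 0 of 22 for nucleotide sugars and 1 and 0 of 14 for fucosylation. In CD4 they were 2 and 0 for N-acetyllactosamine, 0 and 1 for sialylation, 3 and 1 for O-glycans, 0 and 1 for N-glycan processing and 3 and 1 for lectins. These groups also hold genes that remove sugars or their modifications. The lysosomal GLB1 is among the higher N-acetyllactosamine genes in CD4 and CD8. In CD8, NEU1 is among the higher and SIAE among the lower sialylation genes. Of 28 oligosaccharyltransferase and early N-glycan genes, which build and attach the N-glycan precursor, edgeR called 0 in either T cell type (6 in CD4 and 4 in CD8 at an unadjusted p under 0.05), as did DESeq2, and 1 was lower in CD8 over the list alone. For CD4 fucosylation and nucleotide sugar genes edgeR called 0 (1 and 3 at an unadjusted p under 0.05) and DESeq2 0 and 1.

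Across cell classes the LEL share of lectin PLA counts was highest in NK cells and monocytes, with CD8 memory-like cells and B cells next. NK cells gave LEL 54.7% in untreated donor 1, 51.4% after ConA and 19.1% in donor 2, and CD8 memory-like cells gave 28.6%, 23.8% and 14.4%. CD8 naive-like cells gave 5.50%, 4.97% and 2.85%, and CD4 naive-like cells 4.90%, 5.81% and 2.94%. LEL took 49.5% and 40.5% in monocytes of donor 1 and donor 2, and B cells gave 8.93%, 30.5% and 14.8%, above CD8 memory-like cells after ConA and in donor 2. PHA-L was highest in CD4 memory-like cells, at 13.0%, 9.93% and 8.81%, against 1.98%, 3.09% and 2.31% in CD8 memory-like cells.

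**Figure D2:**
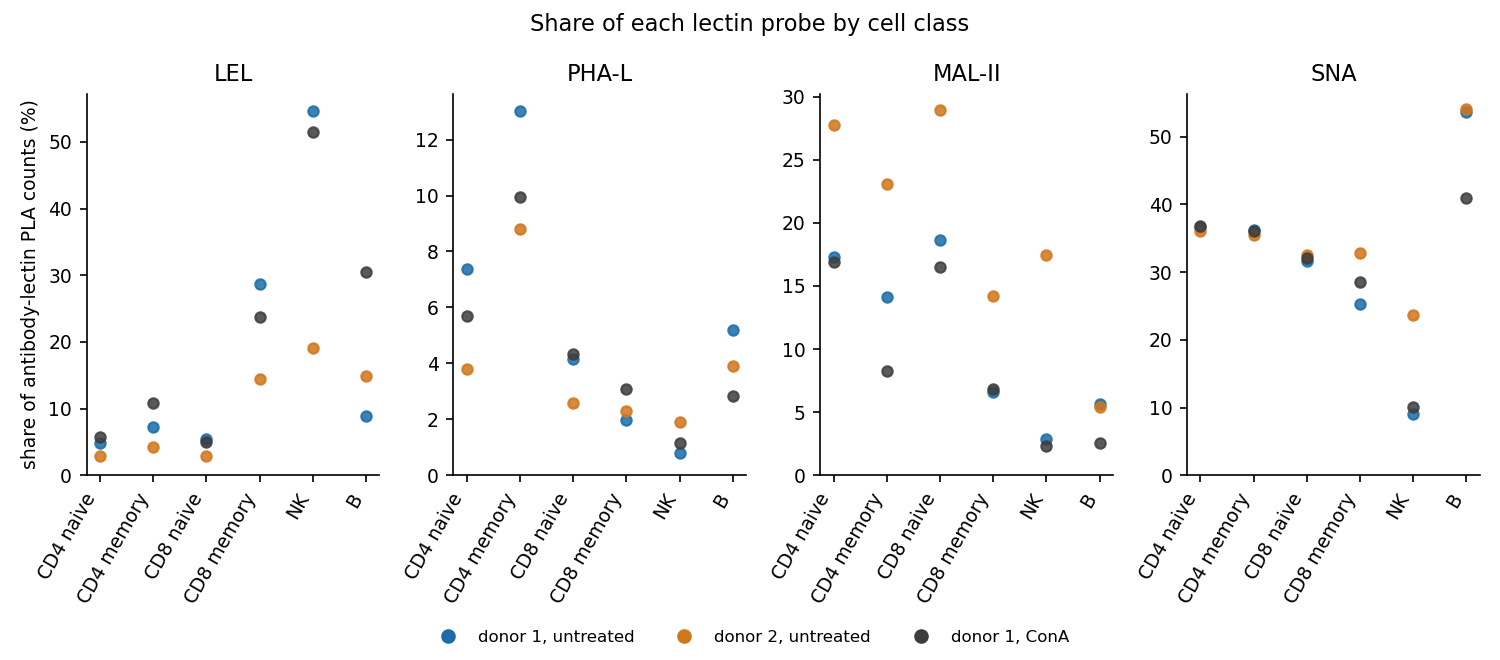
Share of antibody-lectin PLA counts (%) taken by LEL, PHA-L, MAL-II and SNA in each cell class and library. Among the classes drawn, LEL stands highest in NK cells, and PHA-L in CD4 memory-like cells at 13.0% in untreated donor 1. Monocytes are not drawn.

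ConA-treated T cells of donor 1 had far more cytokine and cell cycle RNA than untreated T cells. IL9 (ENSG00000145839), a T helper cytokine, went from 9 to 13991 counts, 1320-fold higher relative to all counts (95% counting interval 695 to 2890). The chemokine CCL3 (ENSG00000277632) was 131-fold (114 to 153) higher and IL21, which drives B cell help, 233-fold (41.4 to 9224). GALR2, a galanin receptor, was 347-fold (118 to 1680) higher, the cell cycle kinase PKMYT1 144-fold (25.6 to 5740), the phosphatase CDC25A 102-fold (34.8 to 499) and the replication factor CDC45 54.5-fold. The zinc finger gene ZBED2 (59.96-fold, 44.4 to 83.0), the G protein subunit GNG8 (63.2-fold) and the growth factor HBEGF (52.2-fold) were also among the highest. The connexin GJB2 went from 0 to 445 counts and IGF2 from 0 to 58, at least 126-fold and 16.4-fold higher with a floor of 3 counts per library. The residency factor ZNF683 (ENSG00000176083) stood lowest at 0.0490 of its untreated level (0.0176 to 0.110), followed by NXPH4 at 0.0665, MYO16 at 0.0734 and the complement receptor CR1 at 0.0980. YPEL4 (0.123), NAV2 (0.127), FRMPD3 (0.129), the Fc receptor-like gene FCRL6 (0.139), FMN1 (0.140), NOG (0.152), NME8 (0.152) and GPR141 (0.154) were lower too. The median of all genes stood at log2 −0.17 in T cells, −0.12 in NK cells and 0.14 in B cells with library totals, and at −0.01, −0.04 and 0.41 with TMM scaling. Each named gene was also at least 2-fold above or below donor 2 untreated cells.

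Activation programs stood above all 10000 random gene lists of equal expression in T cells. The median was log2 1.82 for activation receptors (13 of 18 at least 2-fold higher), led by the costimulatory TNFRSF9 (46.8-fold) and the IL-2 receptor chain IL2RA (26.6-fold, 25.3 to 27.9), with TNFRSF4 at 24.3 and CTLA4 at 12.1. TMM scaling gave 1.99 for that list. Activation transcription factors had a median of 1.57 (14 of 21; EGR3 23.5-fold, BATF3 16.7, EGR2 15.8) and cytokines 2.54 (22 of 27; IL10 32.6-fold). Cell cycle genes had 2.39 (25 of 28; GINS2 15.5-fold, UBE2C 14.8, TYMS 12.9), ribosome biogenesis 1.83 (19 of 22; NOP16 7.05, BOP1 6.31), glycolysis 1.11 (12 of 21; TPI1 6.43, HK2 5.45) and endoplasmic reticulum chaperones 1.12 (10 of 20; CALR 5.25, MANF 5.10). Cytotoxic genes had 0.60 (percentile 99.2), with GZMB 21.7-fold higher (21.2 to 22.2) and GZMK at 0.252, and heat shock genes 0.49 (percentile 98.9; HSPD1 9.06, HSPE1 7.55). Interferon response genes stood at −0.28 (percentile 11.7; MX2 0.447, IFI27 2.01), interferon-γ targets at 0.06 (percentile 79.7; IDO1 0.187, WARS1 5.11) and mitochondrially encoded genes at −0.48 (percentile 3.23; MT-CYB 0.511). Platelet and red cell RNA hardly differed, with TUBB1 at 1.28, ITGA2B at 0.911, SLC25A37 at 1.06 and ALAS2 at 1.05 of the untreated level.

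**Figure D3:**
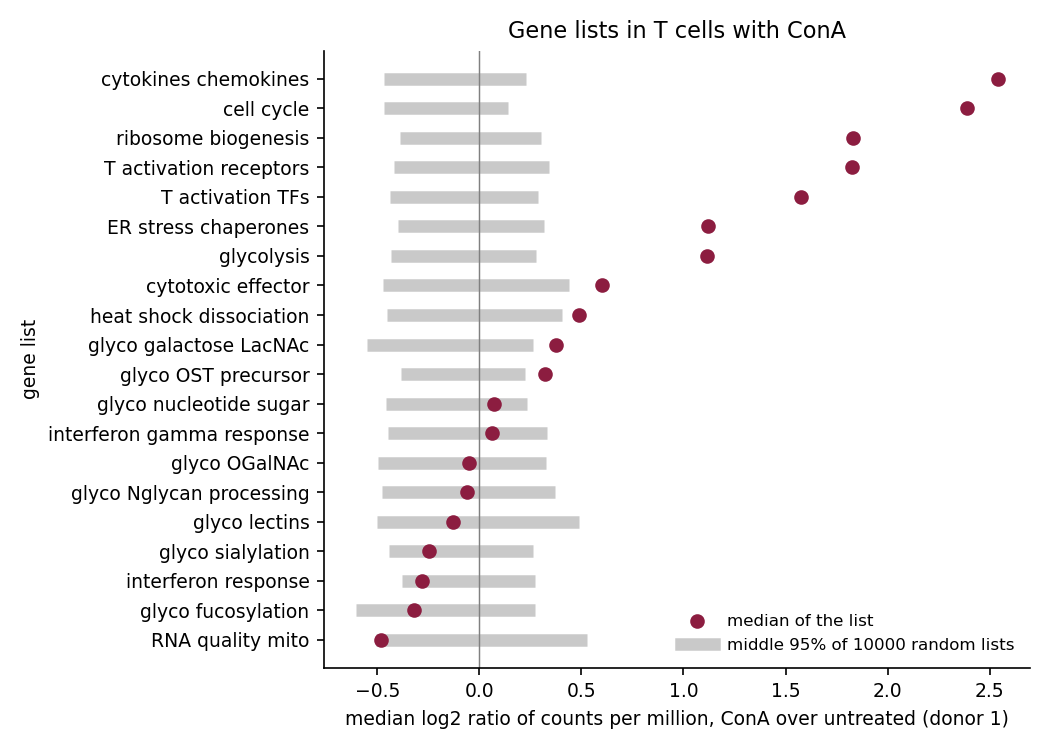
Median log2 ratio of ConA over untreated T cells of donor 1 (CPM) for each gene list, with grey bars for the middle 95% of 10000 random lists. Cytokines (2.54) and cell cycle genes (2.39) stand furthest to the right, and most glycosylation lists lie within the grey.

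Glycosylation RNA in T cells moved little as a whole after ConA, with single genes at either extreme. Oligosaccharyltransferase and early N-glycan genes had a median of log2 0.32 (percentile 99.3; ALG3 2.67-fold, DPM2 2.09, TMEM258 1.91, OSTC 1.90) and N-acetyllactosamine genes 0.38 (percentile 99.3), led by the galactosyltransferase B4GALT2 at 7.45-fold. Medians were −0.06 for N-glycan processing (percentile 63.1; MGAT5B 0.297, MAN2A2 2.51, MGAT4A 0.412), −0.25 for sialylation (percentile 25.2; ST8SIA1 0.290, NANP 2.85, ST6GALNAC2 0.432) and −0.05 for O-glycans (percentile 66.5; GALNT4 2.44, C1GALT1C1 2.17). Fucosylation stood at −0.32 (percentile 29.8), although FUT7, which makes selectin ligands, was 4.53-fold higher and GFUS 2.54-fold. Nucleotide sugar genes stood at 0.07 (percentile 87.5; GMPPB 3.18, SLC35B1 2.86) and lectin genes at −0.13 (percentile 42.1; KLRB1 0.236, LGALS1 2.56).

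Activation and growth lists stood high after ConA in NK cells, and some of them in B cells. In NK cells the effector cytokine IFNG was 339-fold higher (308 to 374), the ribonucleotide reductase RRM2 213-fold, HBEGF 130-fold and the replication factor MCM10 64.8-fold, and GPR84 went from 0 to 149 counts, at least 65.4-fold. ZNF541 (0.0329), A2MP1 (0.0399), PZP (0.0645), FCRL6 (0.0646) and the protease inhibitor A2M (0.0693) were lowest, and A2MP1 is a pseudogene whose reads may belong to A2M. NK cytokines had a median of log2 3.23 (11 of 12), cell cycle genes 2.997 (24 of 24) and chaperones 1.74 (13 of 19), each above all random lists, as were heat shock and dissociation genes (1.27, 8 of 15), whereas interferon response genes stood at −0.63, below all of them. In B cells the interferon-induced chemokines CXCL10 and CXCL9 went from 0 to 713 and 665 counts, at least 66.4-fold and 62.0-fold higher, and the cyclin CCND2 was 190-fold higher. IFNG (0 to 123 counts, at least 11.5-fold) also appeared there, but NK cells held 108258 IFNG counts and free RNA was not ruled out. SNHG4 was at least 6.06-fold higher, and SSPN (0.00799), the ephrin receptor EPHA4 (0.0175), CSGALNACT1 (0.0259), TBC1D9 (0.0299) and TEX9 (0.0559) were lowest in B cells. B cell ribosome biogenesis genes had a median of 2.11 (17 of 18) and activation transcription factors 1.92, beside heat shock and dissociation genes at 1.90 (6 of 9). B cell cycle genes (median 1.10, percentile 73.7, 5 genes) and activation receptors (0.88, percentile 96.1, 5 genes) lay within the range of random lists. Monocytes were not compared, since no cluster of the ConA library was named so.

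On the cell surface ConA-treated T cells carried more of the induced receptors than untreated cells. LAG-3, an inhibitory receptor, went from 0.316 to 7.96 PLA counts per cell, 25.2-fold (24.2 to 26.3), and CD25, the IL-2 receptor chain, from 0.557 to 10.7, 19.2-fold (18.6 to 19.8). The costimulatory CD137 was 18.3-fold (16.3 to 20.6) higher, the inhibitory receptor TIM-3 11.6-fold (10.8 to 12.5), the signalling lymphocyte receptor CD150 3.52-fold and the CD40 ligand CD154 2.79-fold. These ratios differed by state, but states were named in each library alone, from RNA that may itself change with ConA. A state may therefore not hold like cells before and after ConA, and part of these differences may be built in. CD137 was 47.5-fold higher in CD8 memory-like cells but stood at 1.13 (0.684 to 1.92) in CD8 naive-like cells. CD154 stood at 5.81 in CD4 memory-like, 0.680 in CD4 naive-like and 1.09 in CD8 memory-like cells. The IL-7 receptor chain CD127 stood at 0.270 and the chemokine receptor CXCR3 at 0.331 of untreated cells. Total PLA counts per T cell were 992 untreated and 622 after ConA, a ratio of 0.627 (0.626 to 0.628). As shares of the library, LAG-3, CD25, CD137 and TIM-3 were 40.2-fold, 30.6-fold, 29.2-fold and 18.5-fold higher. Among probes with at least 100 counts CD25 was the top probe of NK cells (21.9-fold) and of B cells (8.65-fold, or 20.5 as a share), and CD137 in B cells went from 0 to 37 counts. Total PLA counts per cell stood at 0.862 of untreated in NK cells and 0.423 in B cells. NK cells also had more CD150 (9.13), TIM-3 (8.86), CD137 (8.14) and LAG-3 (4.09) and less CXCR4 (0.181) and CXCR3 (0.267). B cells had more LAG-3 (7.55, from 4 to 105 counts) and CD150 (7) and less of the memory marker CD27 (0.0623), CXCR4 (0.127), CD29 (0.157) and MAL-II (0.215) per cell. As shares these 4 stood at 0.147, 0.301, 0.370 and 0.509. T cell proteins also stood higher per B cell, such as CD4 (1.86), CD2 (1.44), CD5 (1.43) and CD7 (1.40), although CD3 (0.917) and CD8 (0.856) did not. LAG-3 gave 0.719 counts per B cell against 7.96 per T cell after ConA, and stray T cell signal was not ruled out for it.

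Over all T cells together, lectin signals after ConA ranged from 0.522 of untreated for PHA-L to 1.17 for PNA. PNA, which binds core 1 O-glycans without sialic acid, gave only 0.111 counts per T cell untreated and 0.130 after ConA. Per cell, the ratios were MAL-II 0.532, MAL-I 0.559, PHA-E 0.611, SNA 0.665, ConA 0.672, LEL 0.693, AAL 0.737, UEA-I 0.767, DSL 0.768, ECA 0.823, DBA 0.859, GSL-II 0.8997 and Galectin-3 0.943. As shares of the library, 10 of the 15 lectins turned from below to above 1, namely SNA (1.06), ConA (1.07), LEL (1.105), AAL (1.18), DSL (1.22), UEA-I (1.22), ECA (1.31), DBA (1.37), GSL-II (1.44) and Galectin-3 (1.504). PNA (1.86) was higher both ways, and PHA-L (0.832), MAL-II (0.848), MAL-I (0.892) and PHA-E (0.974) lower both ways, over all T cells together. Of the 4 states, which may not hold like cells before and after ConA, PNA was higher per cell only in CD4 memory-like cells (3.12). It stood at 0.597 in CD8 memory-like and 0.577 in both CD4 and CD8 naive-like cells. PHA-L was higher in CD8 memory-like cells (1.08 per cell, 1.61 as a share), against 0.530 per cell in CD4 memory-like cells. NK cells ranged from MAL-II at 0.663 and UEA-I at 0.723 to Galectin-3 at 1.65 and PNA at 2.80, with MAL-I 0.799, LEL 0.809, DBA 0.885, SNA 0.943, DSL 1.00, ConA 1.04, AAL 1.06, PHA-E 1.06, PHA-L 1.15, GSL-II 1.45 and ECA 1.54 between, and DBA (1.03) and SNA (1.09) turned as shares. In B cells LEL was highest at 1.40 (3.32 as a share), then Galectin-3 1.19, MAL-I 0.734, ECA 0.508, AAL 0.458 (1.08 as a share), DSL 0.356, ConA 0.356, SNA 0.352, PHA-E 0.248 and PHA-L 0.245, and ECA (1.20) and MAL-I (1.74) also turned as shares. B cell counts of UEA-I (1 and 3, untreated and ConA), PNA (3 and 10), GSL-II (5 and 4) and DBA (10 and 9) were too few to place them.

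**Figure D4:**
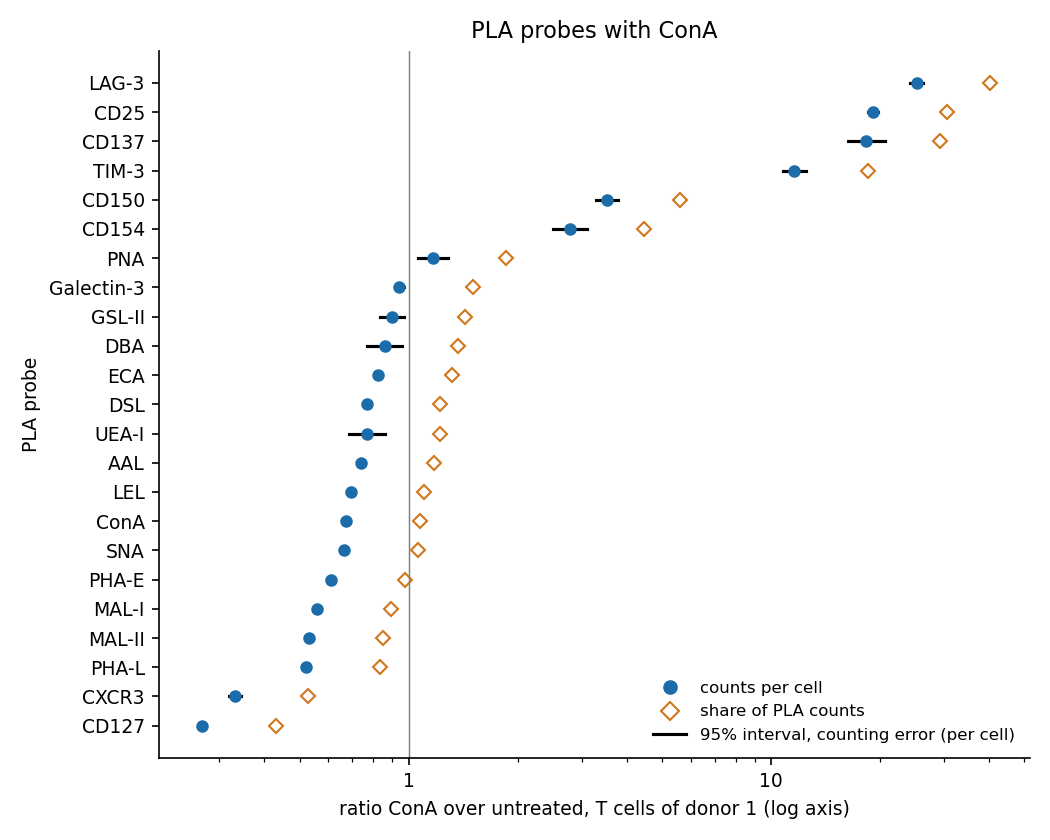
Ratio of ConA over untreated T cells of donor 1 for PLA probes on a log axis, as counts per cell (circles, 95% counting intervals) and as shares of the library (diamonds). LAG-3 (25.2) and CD25 (19.2) stand highest, and most lectins lie below 1 per cell but above 1 as shares.

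The induced receptors were seen with many lectins at once. The top T cell pairs after ConA were LAG-3 with AAL (70.8-fold), LEL (42.4) and ECA (38.9), CD25 with Galectin-3 (70.3) and ECA (40.1), and CD137 with LEL (59.4), AAL (58.8), MAL-I (54.8), DSL (52.9) and SNA (37.2), of 399 pairs with enough counts. NK cells (234 pairs) had CD25 with MAL-I (55.4), SNA (27.5), DSL (23.3), LEL (20.2), PHA-E (18.9) and ConA (16.7), LAG-3 with SNA (20.4), TIM-3 with PHA-L (16.6) and ConA (11.9) and CD150 with LEL (13.5). In B cells (76 pairs), where the total per cell was itself 0.423 of untreated, lower pairs included CD27 with SNA (0.0455), CD29 with SNA (0.0991), PHA-E (0.103) and ConA (0.105), CXCR4 with SNA (0.101) and HLADR with MAL-II (0.118), and CD25 with LEL was 16.9-fold higher.

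Some proteins met particular lectins more or less often than the levels of the 2 probes in each T cell predict. CCR7 was seen with MAL-I 2.85, 2.70 and 2.84 times as often as predicted in donor 1 untreated, donor 1 ConA and donor 2. HLADR with MAL-II stood at 0.270, 0.294 and 0.268, CD11c with PHA-L at 0.266, 0.281 and 0.307 and CD11c with MAL-II at 0.287, 0.354 and 0.305. With margins pooled over cells the CD11c pairs stood lower, at 0.129, 0.130 and 0.209 with PHA-L and 0.151, 0.157 and 0.216 with MAL-II. CD11b with MAL-II (0.372, 0.356, 0.455), CD20 with MAL-II (0.234, 0.378, 0.487) and CD20 with MAL-I (0.307, 0.346, 0.480) were also under 1 in all 3. The CD20 pairs rested on 60 and 48 counts in untreated donor 1. CD20 gave 0.326 PLA counts per T cell there against 9.40 per B cell, and stray B cell signal was not ruled out. In the same library HLADR gave 5.76 per T cell against 213 per B cell. CD11c gave 1.52 per T cell against 11.1 per NK cell, CD11b 3.24 against 20.3 and CD16 0.476 against 37.5. PHA-L and MAL-II took 0.774% and 2.56% of PLA counts in NK cells, against 6.58% and 10.6% in T cells. Stray signal of other cells was therefore not ruled out for these antibodies either. CD16 with PHA-L varied more, at 0.140, 0.263 and 0.678 (0.0850, 0.130 and 0.356 with pooled margins, and 0.0686, 0.454 and 0.873 after thinning), and CD16 with MAL-II stood at 0.341, 0.719 and 0.708. LAG-3 with Galectin-3 (3.61, 1.08, 2.57) rested on 12, 236 and 1 counts. Of 205 pairs with at least 100 counts in each library, 59 stood above 1 and 93 below 1 in all 3, over a range of 0.268 to 4.74. Only 32 of the 205 lay beyond 1.5-fold in donor 1, and unchanged simulated pairs themselves spanned 0.852 to 1.10.

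**Figure D5:**
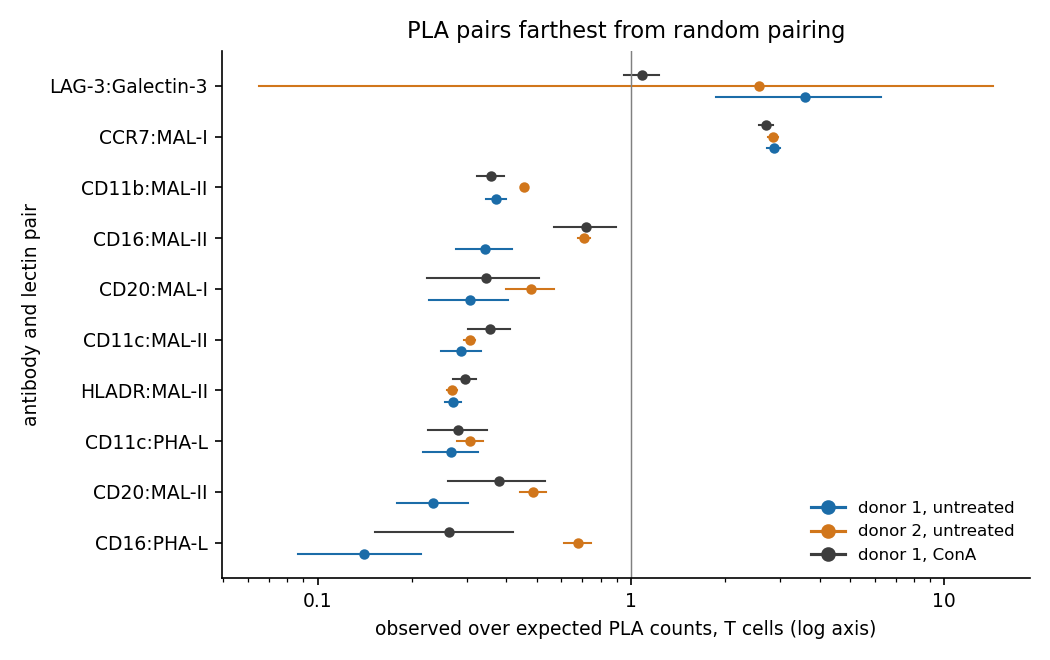
Observed over expected PLA counts in T cells on a log axis for 10 antibody-lectin pairs in the 3 libraries, with 95% counting intervals. CCR7 with MAL-I lies near 2.8 in each library, while CD16 with PHA-L runs from 0.140 to 0.678.

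Untreated T cells of donor 2 differed from those of donor 1 by lower interferon and cytokine RNA and higher heat shock RNA. Interferon response genes, which defend against viruses, had a median of log2 −2.56 (20 of 24 at or below 0.5-fold; IFI44L 0.0188, OAS1 0.0339, RSAD2 0.0431), below all random lists, or −2.24 with TMM scaling. Interferon-γ targets stood at −1.55 (14 of 18; GBP5 0.0630, GBP1 0.0946) and cytokines at −1.83 (13 of 19). IL17F (0.00388), IL22 (0.00668) and IL17A (0.0147), the cytokines of T helper 17 cells, were far lower, and the chemokine CCL2 went from 82 to 0 counts, at least 32.3-fold lower. Heat shock genes had a median of 2.52 (15 of 15), led by HSPA1A at 31.4-fold, HSPA1B at 29.97 and HSPH1 at 18.2, with the immediate early gene FOSB at 34.0. The Notch target HES4 was 237-fold higher (125 to 520), SCGB3A1 191-fold and HSPA6 80.8-fold, and SLC38A3 went from 0 to 58 counts, at least 16.3-fold. The median of all genes stood at −0.40 with library totals and −0.08 with TMM scaling. Donor 2 monocytes also had lower cytokine RNA (median −3.83, 17 of 17) and interferon-γ target RNA (−3.32, 18 of 19) and higher heat shock RNA (2.38, 8 of 15). There CCL2 was at least 1570-fold lower, the metallothioneins MT1G and MT1H 731-fold and 407-fold lower and the chemokines CXCL5 and CCL8 388-fold and 373-fold lower. HES4 was at least 93.1-fold higher in monocytes, MEG3 57.1-fold, LYPD2 42.1-fold, LIPN 34.4-fold and PDE7B 29.2-fold. Monocytes numbered only 35 and 147. Donor, run, handling and, in monocytes, the mix of cells in the class may each account for any of these gaps.

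PLA totals over shared probes were 563 per T cell in donor 1 and 1483 in donor 2, a ratio of 2.63. TIM-3 (10.6-fold, or 4.01 as a share), CD16 (5.92), CD38 (5.11), MAL-II (4.80, or 1.82 as a share), CD27 (4.52), CD11b (4.28), CD28 (4.21) and CD3 (3.99) stood highest in donor 2 T cells. GSL-II (3.55), ECA (3.37), DSL (3.14), SNA (2.98) and AAL (2.74) were higher per cell and as shares (1.35, 1.28, 1.19, 1.13 and 1.04). DBA (2.52), ConA (2.27) and MAL-I (2.19) were higher per cell but lower as shares (0.958, 0.863 and 0.832), and PHA-L (1.78), LEL (1.38) and PNA (1.27) likewise (0.677, 0.522 and 0.481). Galectin-3 was lower both ways (0.787 and 0.299). The top T cell pairs joined TIM-3 with MAL-II (22.5-fold), SNA (14.6) and AAL (14.0), CD16 with SNA (19.5), MAL-II (19.4), PHA-L (16.3), ConA (16.1) and AAL (15.4), CD38 with MAL-II (13.5) and CD44 with CTLA-4 (22.7), of 285 pairs.

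Monocytes of donor 2 carried more CD16 (8.59-fold) and CD11c (4.56) and less CD25 (0.0384), the lipopolysaccharide receptor CD14 (0.159), ICAM-1 (0.262), CD8 (0.294, but 1.29 by the median over cells) and CCR7 (0.302) per cell, with total PLA counts 1.18-fold those of donor 1. Whether the 147 donor 2 and 35 donor 1 monocytes hold the same mix of cells was not tested, so these values may not compare like cells. SNA (2.43), MAL-II (1.77), AAL (1.497), GSL-II (1.48) and DSL (1.17, or 0.991 as a share) were higher, LEL (0.996), ECA (0.994), PNA (0.952), ConA (0.917), MAL-I (0.901) and DBA (0.779) near or below 1, and PHA-L (0.622) and Galectin-3 (0.251) lower. Their leading pairs were CD16 with AAL (29.0, from 1 to 122 counts), SNA (16.8), MAL-II (10.1) and DSL (7.04), CD11c with SNA (16.6), MAL-II (11.1) and AAL (8.04), and, lower, CD25 with LEL (0.0216) and ICAM-1 with ECA (0.134), of 114 pairs.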

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

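The tests in this part were chosen after the results were seen, except LEL at a fixed PLA depth.

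CD8 and CD4 memory-like cells moved apart in their lectin and receptor signals when the difference of the 2 changes was tested in the fit of 8 sums (edgeR quasi-likelihood, Benjamini-Hochberg over 44 probes). The lectins MAL-II (log2 −1.50, adjusted p = 0.0126), PHA-L (−2.11, adjusted p = 0.0135), ECA (−1.40, adjusted p = 0.0230) and DSL (−1.09, adjusted p = 0.0247) moved further down in CD8, and LEL (1.29, adjusted p = 0.0150) and MAL-I (1.03, adjusted p = 0.0212) further up. Among receptors, CD56 (3.63, adjusted p = 0.0135), CD38 (2.87, adjusted p = 0.0275) and CD11c (1.76, adjusted p = 0.0436) stood higher in the CD8 change, and CD27 (−1.43, adjusted p = 0.0177) and CD28 (−2.13, adjusted p = 0.0177) lower. Cytotoxic genes could name CD8 memory-like clusters, whereas cytotoxic CD4 clusters got no state. A difference between CD8 and CD4 cells therefore cannot be told apart here from one between effector and other memory cells.

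The shift of CD8 memory-like cells to LEL was not a matter of which proteins were counted, since within products of CD44 alone the LEL share rose by log2 2.10 in donor 1 and 2.35 in donor 2. Cells thinned to 200 PLA counts still differed by 2.35 and 2.30, which argues against depth per cell, although 246 memory-like and 79 naive-like cells of donor 1 fell under that depth. NK cells hidden in the class would need a share of 0.471 in donor 1 and 0.713 in donor 2. RNA of FCER1G, the lowest NK marker, allows 0.00934 and 0.00638, so the need exceeds that allowance by 50.4 and 112 times. Other NK markers allow more, such as TYROBP (0.106 and 0.279), NCR1 (0.378 and 0.571) and KLRD1 (0.337 and 0.823). Hidden NK cells like those of the NK class would bring all of them, but NK cells low in FCER1G were not ruled out. More poly-N-acetyllactosamine on these cells is a candidate explanation that was not tested. DSL, a lectin for GlcNAc oligomers, and ECA, which binds terminal N-acetyllactosamine, fell in the same cells.

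PHA-L went up in CD4 and down in CD8 memory-like cells in both donors, with counts per cell and with library totals alike, and the smallest gap between the CD4 and CD8 changes was log2 1.38, which argues against scaling. The CD8 fall in donor 2 was small on these scales (−0.22 and −0.17), and the CD8 call itself was lost with library totals (adjusted p = 0.125; over all alternatives 0.00164 to 0.125). Of the 27 PHA-L pairs compared here, 22 (81.5%) had a higher CD4 than CD8 change, so the direction was not limited to 1 protein. Pairs were counted alike whatever their counts, so how much of the PHA-L gap any 1 protein supplied was not tested. MGAT5, whose enzyme makes the branch that PHA-L binds, moved the same way (CD8 minus CD4 change log2 −1.26, unadjusted p = 0.0224), which is consistent with a share in the difference, but its adjusted p over all genes was 0.296. Whether MGAT5 activity differs between the states was not analysed here.

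The total of PLA counts per T cell after ConA was 0.627 of the untreated total, and 0.622 without products of the ConA probe, so added ConA covering the sites of that probe does not account for it. Lectin ratios ranged from 0.522 for PHA-L to 0.943 for Galectin-3, with PNA at 1.17 on few counts (0.111 and 0.130 per cell). A common factor for all probes does not give that range. The drop of the total itself cannot be told apart from a difference in library depth, since each condition had 1 PLA library. A biological loss of surface signal stays open and untested.

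Some antibodies present only in the donor 2 run gave signal whose lower 95% limit lay above 2 times the highest isotype control, in data that no comparison used. TIGIT, an inhibitory receptor of lymphocytes, gave 1.20 PLA counts per T cell and 1.73 per NK cell, and VISTA, a checkpoint ligand of myeloid cells, 0.432 per T cell, 0.877 per NK cell and 21.3 per monocyte. The highest isotype, IgG2a, gave 0.133, 0.181 and 1.77 in T cells, NK cells and monocytes. LFA-1 in NK cells (0.386) was 2.13 times the isotype, with a lower limit of 0.299 that did not clear the bar. In B cells TIGIT (0.290) and VISTA (1.06) stayed below the isotype (1.97).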

How the results depend on the processing

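Chosen after the data were seen were the looser cell filter and doublets kept for T cell states, leaving out the top 1% of cells, and shares, thinning and medians for donor 2.

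The CD8 results were the steadier ones: probes past the threshold ranged from 19 to 27, pairs from 139 to 190 and glycosylation genes from 31 to 42, apart from the fit without the block given next. No named T state result past the threshold reversed direction, and 446 of 504 probe, 244 of 260 pair and 411 of 484 RNA values kept their side of the threshold. Values near the middle could still change sign. SNA in CD4, slightly lower in memory-like cells with TMM scaling, gave 309 memory-like and 276 naive-like counts per cell in untreated donor 1. DESeq2 gave 16 and 27 probes, 82 and 165 pairs and 15 and 34 genes in CD4 and CD8. CD4 counts moved more. Against 11 CD4 probes there were 6 with relative log expression scaling, 18 with the ConA sample as a further block, 4 with joint clustering, 5 with doublets kept and 17 with cell numbers as library size. Against 66 CD4 pairs there were 128 with the ConA block and 37 with joint clustering, and against 12 CD4 genes there were 21 without the filter, 19 with the ConA block and 6 with joint clustering. The ConA block is a further library of donor 1 and adds no donor. Leave-one-out left no residual degrees of freedom and gives values per donor only. The cause of these moves was not tested.

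Without the donor block, counts past the threshold of edgeR's quasi-likelihood test were 4 and 15 for probes in CD4 and CD8, 0 and 41 for pairs and 0 and 1 for glycosylation genes. At an unadjusted p under 0.05 these fits held 11 and 18 probes, 47 and 107 pairs and 11 and 24 genes, and DESeq2, run with the block, gave 82 CD4 pairs and 15 CD4 genes. No paired analysis was possible because ConA and donor comparisons had 1 library per arm.

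The NK share after ConA was 10.8% and 11.6% with doublets kept. With TMM scaling the T cell median of activation receptors was 1.99 in place of 1.82, and that of interferon response genes in donor 2 was −2.24 in place of −2.56. CD25 in T cells after ConA was 19.2-fold per cell, 19.8 with joint clustering, 30.6 as a share and 29.2 after thinning, which left out 2535 ConA and 936 untreated cells. CD16 with PHA-L in untreated donor 1 stood at 0.140 of its expected count, 0.0850 with pooled margins and 0.0686 after thinning, but in donor 1 ConA it was 0.263, 0.130 and 0.454. Between counts per cell and shares, 10 of 15 lectins in T cells after ConA, 2 in NK cells and 5 in B cells crossed 1, of which UEA-I and PNA in B cells rest on 10 counts or fewer per library. Alternatives were run on the named probes, and among their PLA ratios at least 2-fold from 1 these turned. AAL in B cells after ConA was 0.458 per cell, 1.08 as a share and 1.15 after thinning. In donor 2 T cells the ConA probe (2.27 per cell) stood at 0.863 as a share and 0.840 after thinning, DBA (2.52) at 0.958 and 0.885 and MAL-I (2.19) at 0.832 and 0.890. The CD8 probe in donor 2 monocytes (0.294) stood at 1.29 by the median over cells. Of probes not named in that way, CD48 (0.480 per cell, 1.14 as a share) and CD11a (0.495 and 1.17) in B cells after ConA turned too, as did CD147 (2.01 and 0.763), CD29 (2.25 and 0.856), CD4 (2.49 and 0.944), CD45RO (2.58 and 0.980) and CD49e (2.10 and 0.798) in donor 2 T cells. For 39 probe ratios, CD25 among them, the median over cells was 0 and gave no value. Of 637 PLA values per cell 223 stayed within their counting interval and 405 moved beyond it, some across 1, and of 1197 gene ratios 1019 stayed. Simulated 2-fold changes were mostly missed in CD4 probes, in pairs and in RNA at the depths and number of donors used here.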

Other observations

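The lineage comparisons in this part were chosen after the results were seen. They fit T, NK and B cell sums of the 2 untreated donors (6 sums, donor as a block, 2 residual degrees of freedom) with edgeR's quasi-likelihood test, Benjamini-Hochberg adjusted.

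NK cells differed from T cells in 3 lectins. LEL rose by log2 2.05 (adjusted p = 0.0397; donors 2.62 and 1.16), while PHA-L (−2.26, adjusted p = 0.0222) and ECA (−2.13, adjusted p = 0.0256) fell. MAL-I (1.21, adjusted p = 0.124), SNA (−1.22, adjusted p = 0.0642), MAL-II (−1.23, adjusted p = 0.157) and DSL (−0.73, adjusted p = 0.309) did not pass. CD56 (5.37, adjusted p = 0.000888) and TIM-3 (3.93, adjusted p = 0.00554) rose and CD3 (−3.36, adjusted p = 0.00441) fell. NCAM1 (CD56) and CD3 chain RNA helped to name these classes, so the CD56 and CD3 results are in part built in.

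Of 17 galactose and N-acetyllactosamine genes tested, 3 were higher in NK cells, B3GNT7 (5.09, adjusted p = 0.000744), B4GALT6 (3.46, adjusted p = 0.00294) and B4GALT1 (1.27, adjusted p = 0.0160), and so was the sialyltransferase ST3GAL4 (3.03, adjusted p = 0.00209). The branching enzyme GCNT4 (−2.76, adjusted p = 0.00702) and ST8SIA1 (−3.88, adjusted p = 0.00170) were lower. B3GNT7 and B4GALT6 also had no counts in CD8 naive-like cells. In B cells against T cells MAL-I fell by 2.68 (adjusted p = 0.00501), and ST6GAL1, which makes the α2,6-sialic acid that SNA binds, rose by 2.92 (adjusted p = 0.0143), while MGAT4A fell (−2.83, adjusted p = 0.00152). SNA took 53.7% of lectin PLA counts in B cells of untreated donor 1 and 54.1% in donor 2, against 32.6% and 34.6% in T cells, but SNA did not pass in that fit (log2 0.56, adjusted p = 0.434).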
